A study of Arabidopsis thaliana with 2 samples.

How the data were processed

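Gene expression was measured in the aerial parts of 14-day-old Arabidopsis thaliana seedlings on 2 Affymetrix arrays, 1 of wild-type Columbia-0 and 1 of the transgenic line GFP-TIE1-15. Per the labels' protocols, seeds were kept at 4 °C for 3 days, and seedlings grew at 22 ± 2 °C with 16 h of light and 8 h of dark. RNA was purified on columns, and 5 µg of total RNA went into the biotin-labelled cRNA of each array.

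The deposited values were probe set signals on a linear intensity scale, for 22810 probe sets on each array. Per the submitters' processing notes, the tools were GCOS 1.0 and MAS5. The scaling target was not given in the sources used here. The mean signal after removal of 2% of values at each end was 500.05 on both arrays, so the deposited intensity values were taken as already scaled and were used as deposited. No detection calls were used here.

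Probe sets were named through the platform's annotation, updated to the locus names and symbols of the TAIR10.1 RefSeq gene table, which was used for names and for which genes neighbour each other. Of the probe sets, 13513 had 1 gene symbol, 503 had several and were not named, and 8730 non-control probe sets were unnamed here, which does not mean that they lack a gene. Of those with 1 symbol, 13436 matched a locus. Where the table gives no symbol, the gene is called by its locus number. A gene with several probe sets took the mean of its log2 values. Among 25 such measured genes, the probe sets of a gene differed by a median of 0.12 and at most 0.54 in log2 ratio.

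From the deposited signals, log2(signal + 50.0) was computed, the pseudocount being 10% of the trimmed mean, and the log2 ratio of GFP-TIE1-15 over wild type was taken. Folds on this scale understate the difference of dim genes. A probe set was measured if its brighter array reached 40% of the trimmed mean, a signal of 200.02, and 11308 non-control probe sets did. Of these, 5939 were named, for 5914 genes. Where only 1 array reached the minimum, this filter fixed the sign of the log2 ratio. With 1 array per genotype there was no test, no p-value and no error, and the difference between genotypes has no replicate check. Probe sets were counted as higher or lower by a fixed rule of size, a log2 ratio of at least 1 in either direction. The local SD is the median absolute deviation, scaled to the SD of a normal distribution, of log2 ratios over the 500 probe sets nearest in mean signal. It describes the spread among genes on these 2 arrays, not the spread between plants.

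Before the data were examined, 33 gene lists, 21 gene families defined by symbol, the processing alternatives and the rule for named genes were fixed. The rule named every measured gene of the TIE family, of the CIN-type TCP genes and of the genes reported as activated by CIN-type TCPs. It also named the 12 genes with the largest ratio in each direction among probe sets specific to 1 gene, and up to 4 genes in every other list. List members came from general knowledge of the species, as locus numbers. One locus, whose symbol in the reference table contradicted the list, was dropped. Lists with at least 3 measured genes, and families with at least 5, had their median set among the medians of 10000 random lists, whose genes were drawn from the 200 genes nearest in mean signal to each member. The percentile describes these libraries and is not a test. A further 8 lists were added after the largest differences had been seen. Genes outside the rule that are named from the families and from the added lists were chosen after their values were seen.

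Scripts were tested on simulated data built from the real signals, with noise of the local SD. For GFP-TIE1-15 against wild type, over 11308 probe sets, the size rule found 52.0% of 100 probe sets given a 2-fold change and 99.0% of 100 given a 4-fold change. A 2-fold change lies on the threshold of the rule, so the 52.0% follows from the construction. The rule took in 0.72% of the 11108 probe sets given no change. The noise came from the spread among genes on these 2 arrays, so 0.72% is not a rate of false calls between plants. Of 200 simulated lists of 20 genes with no shift, among 5914 genes, 2.5% fell outside the middle 95% of random lists. All 200 lists shifted by 0.5 lay above it. In these simulations the genes varied independently and every list had 20 genes. They do not show how the percentile behaves for genes that vary together or for smaller lists.

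The alternatives were quantile normalization, division of each array by its median, a loess trend on mean log2 signal, a pseudocount of 1 or of 25% of the trimmed mean, no brightness minimum or one of 100% of the trimmed mean, and removal of probe sets that several genes can share. For counts, a further rule took probe sets beyond 3 local SDs of the local median, and for lists the mean replaced the median. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

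TIE1 itself could not be reported: no probe set was named for it, for the other TIE genes, for the TOPLESS corepressors or for the CIN-type TCP genes, and they are not analysed here. The planned check of the transgene on the array was therefore not made.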

Results

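The data were 2 arrays of the aerial parts of 14-day-old seedlings, 1 of wild type and 1 of GFP-TIE1-15, a line carrying a GFP-TIE1 transgene. TIE1 is known as a protein that binds TCP transcription factors of the CIN type, which act in leaf development, and recruits TOPLESS corepressors to them. The comparison addresses which transcripts differ in shoots of the transgenic line. The median signal was 169.3 on the wild-type array and 173.05 on the GFP-TIE1-15 array. A signal of at least 200.02 was reached by 10712 and 10747 probe sets. With 1 array per genotype, none of the differences has a replicate check. Their number limits the precision of every value.

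The cysteine proteinase gene CP1 and the cytokinin response regulator RR16 were higher in GFP-TIE1-15, and AT3G22240, the lipid transfer protein gene AT4G12490 and the anthocyanin synthesis gene DFR were lower. Among 11308 measured probe sets, 136 were at least 2-fold higher in GFP-TIE1-15 and 270 at least 2-fold lower. The counts depended on the pseudocount, with 209 higher and 346 lower at a pseudocount of 1, and 75 and 196 at one of 25% of the trimmed mean. With a brightness minimum of 100% of the trimmed mean, the counts were 83 higher and 178 lower. Of the 136 higher and 270 lower probe sets, 69 and 115 belonged to named genes. Log2 signals on the arrays correlated across the 11308 measured probe sets with a Pearson's r of 0.946, and genes are not independent replicates. Over the same probe sets the median log2 ratio was 0.01, and the robust SD was 0.33 overall and 0.39 among the 2827 dimmest.

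CP1 (AT4G36880), a cysteine proteinase, had a signal of 87.7 in wild type and 1586 in GFP-TIE1-15, a log2 ratio of 3.57. AT1G29090, a papain-type cysteine proteinase gene, had 5.3 and 539.7 (3.42), and DELTA-VPE (AT3G20210), a vacuolar processing enzyme, had 29.2 and 233.8 (1.84). ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, had 4.7 and 280.9 (2.60). The polygalacturonase-type gene AT3G15720 had 84.7 and 798.5 (2.66), and AT2G28510, which encodes a Dof zinc finger protein, had 223 and 1175 (2.17). The glutaredoxin gene AT4G15680 had a ratio of 1.87. The other genes of the 12 were AT2G23970 (2.58), AT5G48290 (2.37), AT1G23100 (1.81), AT1G43590 (1.80) and AT3G49320 (1.79). The ratios of genes with a dim wild-type signal depended on the pseudocount. With a pseudocount of 1 they were 6.42 for AT1G29090, 5.63 for ICL, 5.53 for AT2G23970, 3.35 for AT5G48290 and 2.96 for DELTA-VPE. With one of 25% of the trimmed mean the same genes were at 2.35, 1.65, 1.64, 1.70 and 1.22. CP1 was at 4.16 with the pseudocount of 1 and at 3.01 with that of 25%.

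Among the named genes, the one furthest below wild type was AT3G22240, with a signal of 7842 in wild type and 637 in GFP-TIE1-15, a log2 ratio of -3.52. The lipid transfer protein gene AT4G12490 had 2678 and 341 (-2.80). Of the same family, AT5G55450 had 1829 and 273 (-2.54) and AT2G37870 had 589.9 and 90.2 (-2.19). The chitinase-type gene AT2G43620 had 2679 and 345 (-2.79), and the legume lectin-type gene AT5G03350 had 1406 and 192 (-2.59). AT3G22060, a cysteine-rich secretory protein gene, had 639.8 and 70.9 (-2.51). MSRB6 (AT4G04840), a methionine sulfoxide reductase, had a ratio of -2.23, and ECS1 (AT1G31580) had 12995 and 2817 (-2.19). AT3G23550, of the MATE transporter family, was at -2.13, the FKBP-type immunophilin gene AT5G48570 at -2.09 and AT5G19240 at -2.08. The ratios of genes dim in GFP-TIE1-15 also depended on the pseudocount. With pseudocounts of 1 and of 25% of the trimmed mean, AT3G22060 was at -3.16 and -1.965, and AT2G37870 at -2.70 and -1.73.

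**Figure D1:**
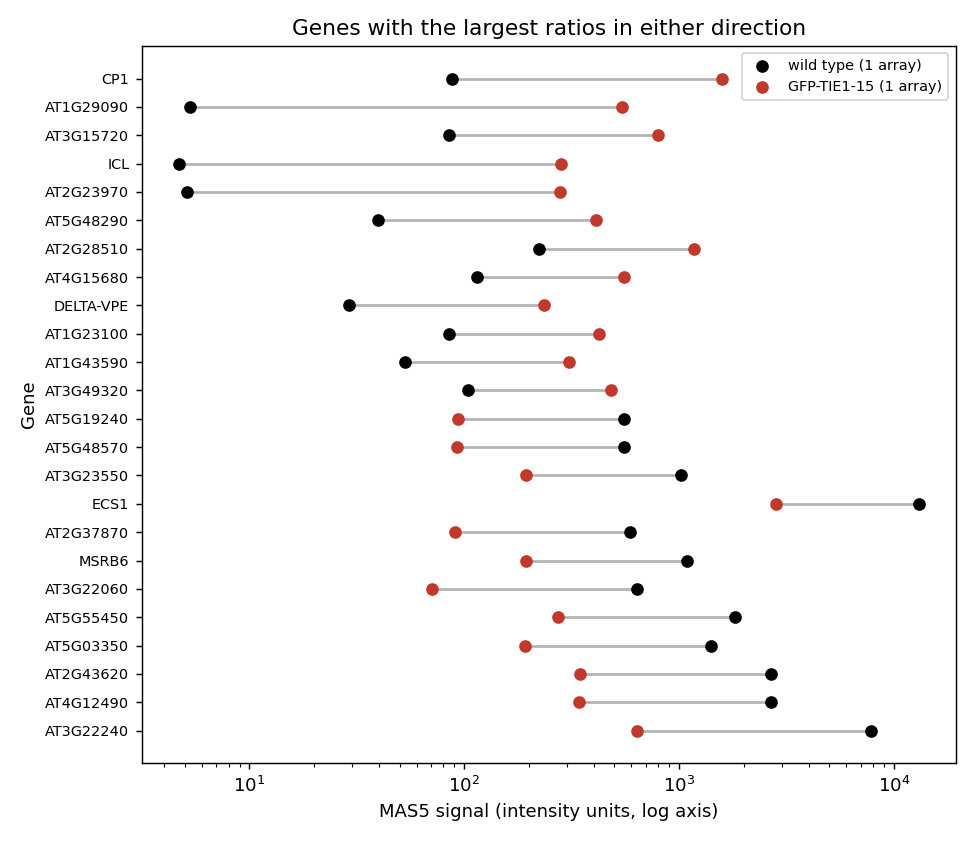
MAS5 signal (horizontal, log axis) of the 12 genes with the largest log2 ratio in each direction (vertical), with 1 point for the wild-type array and 1 for the GFP-TIE1-15 array. CP1 lies at 87.7 in wild type and 1586 in GFP-TIE1-15, and AT3G22240 at 7842 and 637.

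Of the 8 genes reported as activated by CIN-type TCPs, 2 were measured. RR16 (AT2G40670), the type-A cytokinin response regulator also called ARR16, had a signal of 109.2 in wild type and 397.3 in GFP-TIE1-15, a log2 ratio of 1.49. This ratio was 1.85 with a pseudocount of 1 and 1.16 with one of 25% of the trimmed mean. HAT2 (AT5G47370), a homeodomain-leucine zipper gene of auxin responses, had 388.8 and 399.5, a ratio of 0.03. RR16 was also the only measured type-A response regulator. Among the other TCP genes, only TCP15 (AT1G69690) was measured, with a ratio of -0.50.

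Of 12 listed leaf polarity genes, only 3 had a named probe set, and these 3 were measured. Of them, 1 was at least 2-fold lower in GFP-TIE1-15 and 2 passed the rule in neither direction. YAB3 (AT4G00180), a YABBY gene of abaxial leaf identity, had 519.1 and 192.6 (-1.23), YAB5 (AT2G26580) was at -0.56 and the HD-ZIP III gene PHV (AT1G30490) at -0.27. Their median of -0.56 lay at percentile 0.81 of random lists, whose middle 95% ran from -0.44 to 0.50.

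Of 15 listed anthocyanin and flavonoid synthesis genes, only 4 had a named probe set and 3 were measured. Of these 3, 2 were at least 2-fold lower. DFR (AT5G42800), dihydroflavonol reductase, had 901.2 and 288.6 (-1.49), the anthocyanin glucosyltransferase AT4G14090 had 436.3 and 135.6 (-1.39) and UF3GT (AT5G54060) was at -0.71. Their median of -1.39 lay at percentile 0.04. AT4G14090 and UF3GT reached the brightness minimum in wild type only, which fixed the sign of their ratios. Of 14 listed senescence genes, only 4 had a named probe set and 3 were measured. Of these 3, 1 was at least 2-fold lower, with WRKY53 (AT4G23810) at -1.36, WRKY6 (AT1G62300) at -0.91 and SAG101 (AT5G14930) at -0.47. All 3 reached the brightness minimum in wild type only, so their place below 0 was fixed by that filter. Their median of -0.91 lay at percentile 1.73, among random medians whose middle 95% ran from -0.88 to 0.76. It was -0.69 with a pseudocount of 25% of the trimmed mean, and -0.69 over 4 genes with no brightness minimum. The 4 reference genes had a median of 0.01, at percentile 38.2, with PEX4 (AT5G25760) at 0.01, AT5G15710 at -0.00, AT4G34270 at 0.26 and AT2G28390 at -0.13.

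In all, 14 lists, those of RR16, HAT2 and TCP15 included, had 1 or 2 measured genes and were given no percentile. The auxin response genes GH3.3 (AT2G23170) and WES1 (AT4G27260), which encode auxin-conjugating enzymes, were at -0.998 and -0.81. OPCL1 (AT1G20510), of jasmonate synthesis, was at -0.81. The cold-responsive genes COR15A (AT2G42540) and COR47 (AT1G20440) were at -1.04 and -0.25, and among the touch and wound genes STZ (AT1G27730) was at -0.60, with WRKY53 above. The clock gene GI (AT1G22770) was at -0.61, and FMA (AT3G24140), the guard cell regulator FAMA, at -0.51. LHCB4.1 (AT5G01530) and RCA (AT2G39730), of photosynthesis, were at -0.33 and -0.35, and at -0.16 and -0.12 after quantile normalization. The floral regulator AGL24 (AT4G24540) was at 0.87, and the expansin genes EXPA4 (AT2G39700) and EXPA8 (AT2G40610) at 0.49 and -0.04. In aliphatic glucosinolate synthesis, UGT74B1 (AT1G24100) was at 0.42 and BCAT4 (AT3G19710) at -0.17. Of 15 root markers, 3 had a named probe set and only PYK10 (AT3G09260) was measured, at 6746 in wild type and 5954 in GFP-TIE1-15 (-0.18). The root markers EXPA7 (AT1G12560) and EXPA18 (AT1G62980) were below the minimum. They had 30.1 and 62.3 in wild type, and 3.8 and 44.3 in GFP-TIE1-15. In 15 lists no gene was measured. No member had a named probe set in the lists of the TIE family, TOPLESS corepressors, CIN-type TCP genes and cell cycle. The same held for gibberellin metabolism, salicylate response, indolic glucosinolates, morning clock, epidermis and vascular genes. The lists of organ boundary and meristem, leaf growth regulators, jasmonate response, auxin synthesis and transport and heat shock had named probe sets. All of those were below the brightness minimum.

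Of the 21 families, 4 had at least 5 measured genes. Families were defined by symbol, and of the 5914 measured named genes only 919 had a symbol other than the locus number. A family with few or no measured genes here is therefore not shown to be weakly expressed. The expansin genes had a median of 0.40 over 6 genes, 5 of them above 0, at percentile 97.49, led by EXPA20 (AT4G38210) at 0.93. The UGT glycosyltransferase genes had a median of -0.25 over 20 genes, at percentile 0.02, with 13 below 0 and none 2-fold apart, and their mean was -0.16. UGT72E1 (AT3G50740) was at -0.92 and UGT76C2 (AT5G05860) at 0.98. The CYP genes had a median of -0.27 over 9 genes, at percentile 1.56, with CYP71B22 (AT3G26200) at -1.37 and CYP71B23 (AT3G26210) at -1.25. Of the 9, 4 lay above 0, and the median of the 7 without a 2-fold difference was 0.00. With a brightness minimum of 100% of the trimmed mean, the median over 4 genes was -0.76. The symbol rule also took in CYP71 (AT3G44600), a cyclophilin at 0.12, which the median and percentile include. The other members were all CYP71B genes, so the list does not stand for cytochrome P450 genes at large. Ribosomal genes named RPL or RPS, all encoded in the plastid, had a median of 0.20 over 15 genes, at percentile 92.8.

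**Figure D2:**
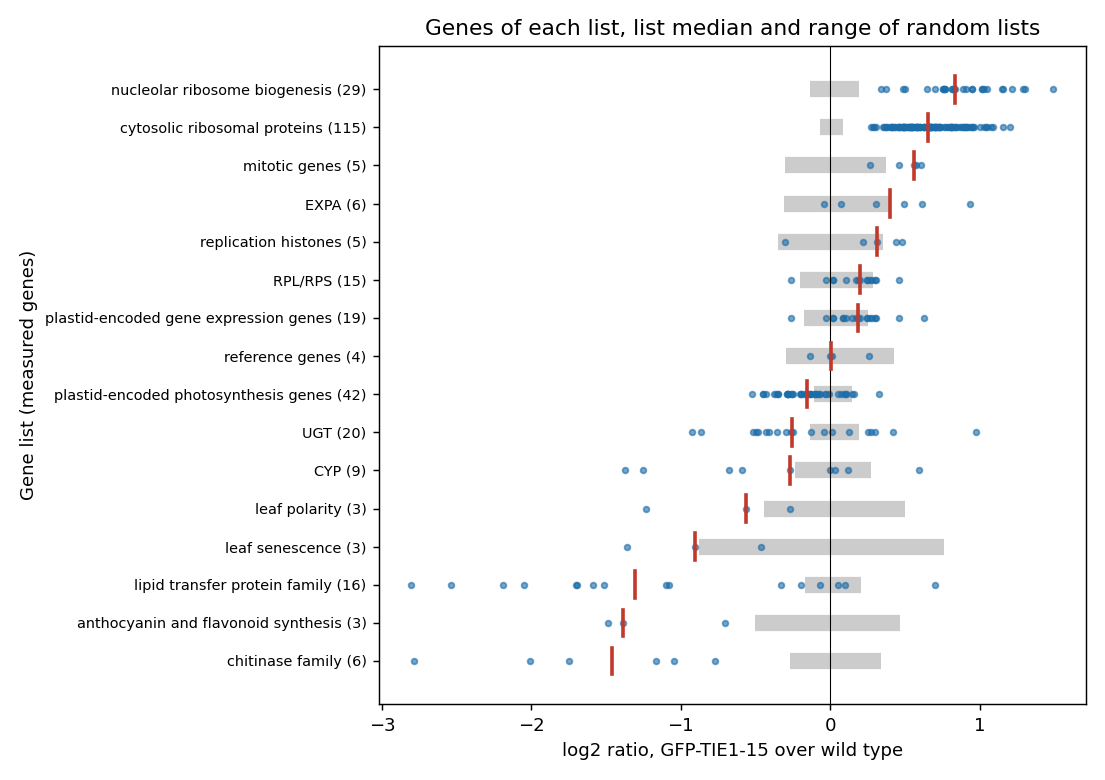
Log2 ratio of GFP-TIE1-15 over wild type (horizontal) for the measured genes (points) of each list (vertical, number of genes in brackets), with the list median (red line) and the middle 95% of medians of 10000 random lists (grey bar). The median of the 115 cytosolic ribosomal protein genes is 0.66 and that of the 3 anthocyanin genes -1.39; the ribosomal, lipid transfer, chitinase, plastid, histone and mitotic lists were added after the largest differences had been seen.

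**Figure D3:**
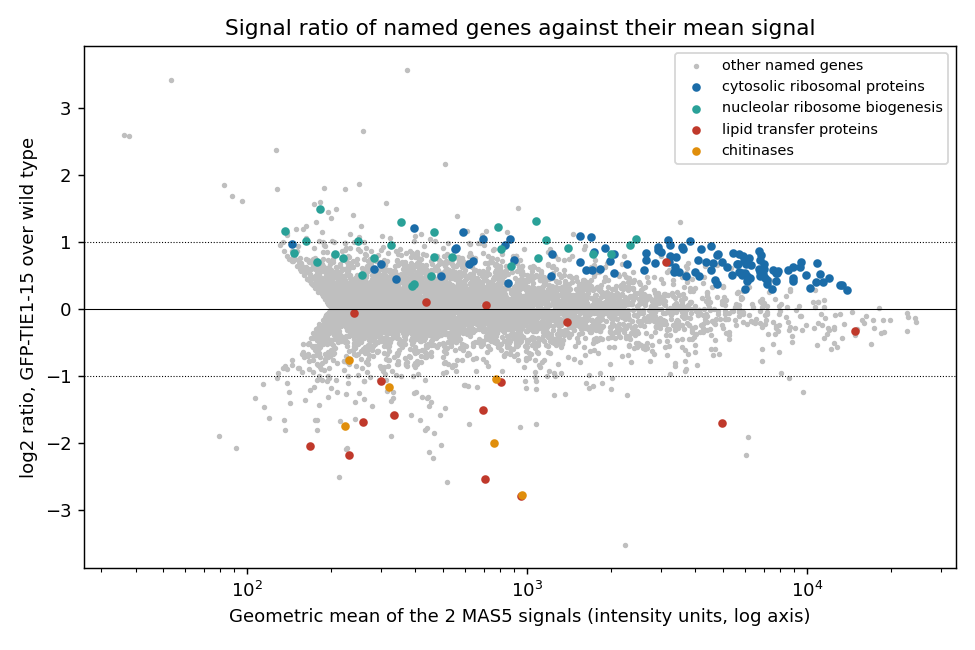
Log2 ratio of GFP-TIE1-15 over wild type (vertical) against the geometric mean of both MAS5 signals (horizontal, log axis) for the 5914 measured named genes (points), with dotted lines at the 2-fold rule. The 4 coloured groups were chosen after the largest differences had been seen: all 115 cytosolic ribosomal protein genes and all 29 ribosome biogenesis genes lie above 0, and 10 of 16 lipid transfer protein genes and 5 of 6 chitinase genes lie at least 2-fold lower.

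Spike-in controls were slightly lower on the GFP-TIE1-15 array. The 12 measured bacterial and phage spike-in probe sets had a median log2 ratio of -0.22, and 11 of them lay below 0. The 13 measured Bacillus probe sets had a median of -0.14. The ratio of 3′ to 5′ signal differed by a median of 0.013 in log2 over 6 control pairs (SD 0.20). For 1 actin pair it was 19.4 in wild type and 14.3 in GFP-TIE1-15, and for 1 GAPDH pair 1.80 and 1.87.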

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

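TIE1 had no named probe set, so no alternative could be run for it, and no senescence gene was left at the minimum of 100%. No paired analysis was possible because each genotype had 1 array. The counts of 136 higher and 270 lower probe sets were 209 higher with a pseudocount of 1, 75 higher with a pseudocount of 25% of the trimmed mean, and 83 higher and 178 lower with a brightness minimum of 100% of the trimmed mean, which leaves 6938 probe sets; the construction of these settings accounts for the direction of each shift. The rule of 3 local SDs gave 143 higher and 260 lower, of which 109 and 218 were also in the main counts. The anthocyanin median of -1.39 was -1.64 with a pseudocount of 1, -1.11 with one of 25%, and -1.05 over 4 genes with no minimum. The CYP median was -0.76 over the 4 genes left by the minimum of 100%, and the UGT mean was -0.16; the cause was not tested. Alternatives for named genes gave 393 values within the local SD and 33 beyond it, all with another pseudocount and the same sign. Each named gene had 1 probe set, so neither the brightness minimum nor the removal of shared probe sets could change its ratio. The values from those settings, part of the 393, tested nothing. The added list medians ranged from 0.62 to 0.67 for cytosolic ribosomal proteins and from -1.55 to -0.33 for lipid transfer proteins under the processing alternatives. Removal of shared probe sets took no gene from the added lists, so it tested nothing for them. The median of all measured probe sets was between -0.01 and 0.01 under each scaling. Dim genes are limited by signal over background, since no detection calls were used.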

Other observations

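The lists in this part were added after the largest differences had been seen, and the tests of RNA degradation, of differences between plant samples, of a stress response and of neighbouring genes were chosen after the result was seen. All 115 measured cytosolic ribosomal protein genes had a log2 ratio above 0, from 0.28 for AT5G20290 to 1.2 for AT5G39850 (247.2 in wild type and 632.8 in GFP-TIE1-15). Their median log2 ratio was 0.66, a fold of 1.58, above all 10000 random medians, of which the highest was 0.17. Only 8 of them passed the 2-fold rule, and the median of the other 107 was 0.63. The 29 measured genes of nucleolar ribosome biogenesis were also all above 0, with a median of 0.83 and 10 at least 2-fold higher, led by AT4G16630 at 1.49 (93.7 and 354.6). Both lists together held 18 of the 69 named genes that were at least 2-fold higher, a share that leaves out unnamed probe sets.

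Of the 16 measured lipid transfer protein genes, 10 were at least 2-fold lower in GFP-TIE1-15 and 3 lay above 0, with AT4G22490 the highest at 0.70. Their median was -1.31, and that of the 6 measured without a 2-fold difference was -0.01. With no brightness minimum the family median over 28 genes was -0.33. All 6 measured chitinase genes lay below 0, 5 of them at least 2-fold lower, with a median of -1.46, and over 15 genes with no minimum it was -0.67. Both lists together held 15 of the 115 lower named genes, a share that also leaves out unnamed probe sets. Both were chosen because their members stood among the lowest genes, so their place below all 10000 random medians describes that choice as well. Plastid-encoded photosynthesis genes had a median of -0.15 over 42 genes, at percentile 0.39, and plastid-encoded gene expression genes 0.18 over 19, at percentile 94.1. Those 19 include all 15 genes of the RPL and RPS family, so their median is not independent of that of the family. Most plastid transcripts lack a poly(A) tail, which limits what their signals show.

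The difference in ribosomal protein genes may come from the arrays, from the plants sampled or from the transgene. In groups of measured probe sets of rising signal, the median log2 ratio fell only from 0.038 to -0.005. Removal of the loess trend could therefore change the list's median little. After it the list's median was 0.66, while the middle 95% of random medians ran from -0.06 to 0.09. The trend seen with signal was thus smaller than the list's difference. Random lists were already matched on signal, and this list was added after the largest differences had been seen. The removal therefore adds no independent evidence on a scaling trend. The 3′ to 5′ ratios of 6 control pairs, for actin, GAPDH and ubiquitin only, differed by a median of 0.013, with pairs from -0.44 to 0.06. The actin pairs were at -0.44 and -0.20. The median lay below the list's median by more than the SD of the pairs, as the rule for no degradation asked. These ratios and a list median are unlike measures, however, so the rule cannot decide on RNA degradation. A labelling bias for short transcripts was not tested. A larger share of dividing tissue stays open: 5 replication histone genes had a median of 0.31, within the middle 95% of random medians (-0.35 to 0.35), and 5 mitotic genes, among them AUR1 at 0.58, had 0.56, above theirs (-0.30 to 0.37), but 0.36 over 13 genes with no brightness minimum. A difference between 2 plant samples that is not due to the transgene cannot be told apart from the genotype with 1 array per genotype.

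For the lower lipid transfer protein and chitinase genes, removal of the loess trend gave medians of -1.33 and -1.50. The median log2 ratio in groups of rising signal fell only from 0.038 to -0.005, so this removal could change the list medians little. The trend seen with signal was thus smaller than these differences. Both lists were chosen for their low members, so the removal adds no independent evidence on a trend with signal. A stress response of the wild-type sample alone could give the same low list medians. With 1 array per genotype it cannot be told apart from an effect of the transgene.

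Of the 115 genes at least 2-fold lower, 15 formed 9 close pairs, at most 5 positions apart among protein-coding genes, among them the chitinase genes AT2G43570, AT2G43590 and AT2G43620. Chance placing of these genes gave a mean of 2.59 pairs over 1000 random placings, and 1 placing reached 9, so by the bound set for it chance was not excluded. Related genes in tandem were not treated apart. The 68 higher nuclear genes formed 2 pairs, against a mean of 0.869 by chance, and 208 of 1000 placings gave as many.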
